A study of Homo sapiens with 6 samples.

How the data were processed

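RNA from the human breast cancer cell line T47D was measured on 6 oligonucleotide arrays, 3 from cells treated with the PI3 kinase inhibitor GDC-0941 for 6 hours and 3 from controls whose agent the labels give as none. The labels do not say whether the controls received the solvent, so each difference may include its effect. Per the labels' protocols, biotinylated cRNA was prepared from 6 ug of total RNA by the standard protocol of the array's manufacturer (Affymetrix). The deposited table holds 54675 probe sets on a log2 scale, 1 column per array. RMA is the one tool named in the submitters' processing notes. It corrects background, normalizes the probe values of the arrays to one distribution and summarises each probe set by median polish. Its version, the software package and the chip definition are not given in the sources used here, and the log2 scale was taken from the values, which lie between 3.00 and 14.81. Values normalized in this way are relative to the other arrays, so a change shared by most transcripts is not visible in them. RMA values carry no detection call, so genes near background were not marked.

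Of the 54675 probe sets, 62 are manufacturer's controls. Among the other 54613, the platform annotation names 1 gene for 41091, several genes for 1801 and no gene for 11721. Symbols were updated through the Entrez identifier for 41037 of the 41091, with the RefSeq gene table of assembly GRCh38.p14. That table was used for names and gene lengths only, because the build behind the chip annotation is not given in the sources used here. Each gene was represented by the probe set with the highest mean over the 6 arrays among those naming only that gene, which gave 19775 genes, 9252 of them with 1 probe set. No filter on dim probe sets was applied.

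Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with GDC-0941 minus control as the contrast and Benjamini-Hochberg adjustment over all 19775 genes. A gene was called at an adjusted p under 0.05, and an adjusted p given for a gene is from this fit unless another setting is named with it. The same fit was made on all 54613 probe sets. The 37 gene sets (29 lists and 8 families defined by symbol) were tested with limma's camera at its preset correlation of 0.01, with adjustment over the 37 sets. This test asks whether a set moved relative to the other genes. Camera with an estimated correlation and fry, which tests a set by itself, were alternatives. Members were counted both over all genes tested and adjusted over the list alone. Lists, test, alternatives and the naming rule were fixed before the data were examined. The rule named the 8 genes with the largest rise and the 8 with the largest fall among called genes whose 3 treated arrays all lay on one side of the 3 controls. It also named 10 genes fixed in advance and, for each list, the 3 called members with the largest change, or the member with the smallest p where none was called. One of these 10 and some list members are not reported here. Members named outside this rule are stated to have been chosen after their values were seen.

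On values simulated from the real means and spreads of the 19775 genes, the fit recovered 20% of 50 genes changed by 0.25 on the log2 scale. It recovered 78% of 50 genes changed by 0.5 and 100% of those changed by 1 or by 2, and 2.61% of its calls were false. Far fewer genes were changed there than were called in the real data, which makes the adjusted threshold stricter, so these shares do not carry over to the real comparison. The precision is limited by the number of arrays, 3 per group. The median standard error of a log2 difference was 0.0641. Nothing in the labels says whether the replicates are separate cultures, so p-values measure the spread between these samples, which may be technical. No pair of columns was identical: values of 2 arrays of a group differed with an SD of 0.118 to 0.166, and arrays of different groups with an SD of 0.218 to 0.266.

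The labels number the replicates 1 to 3 in both groups and do not say that a number marks a shared day or culture. No pairing was used in the comparison. The alternatives were a replicate block, leaving out each array, quantile normalization again, centring on the array median, a variance trend with robust estimation, array weights, a filter on the level, other rules for choosing the probe set and an adjusted p under 0.01. Centring each array on its 18 hybridisation control probe sets (for bacterial and phage transcripts added before hybridisation) and the array's overall spread as a covariate were added after the data were examined. Random lists matched on mean expression, 10000 per list, and refits on all 10 splits of the 6 arrays into 3 and 3 served as further checks. Figures were drawn with matplotlib 3.10.9.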

Results

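T47D is an established human breast cancer line of luminal type that carries the oestrogen receptor. GDC-0941 inhibits all class I PI3 kinases, the lipid kinases that activate AKT downstream of growth factor receptors. Transcript levels were compared between 3 arrays from cells treated with GDC-0941 for 6 hours and 3 arrays from control cells given no agent per the labels, which do not say whether these received the solvent, to find which transcripts respond to PI3 kinase inhibition. The labels give the dose as 1 mM. The unit is printed as written, but it is uncertain: a micro sign may have been lost, in which case the dose was micromolar, and the array values cannot settle this. Values are log2 RMA signals of the deposited table. The array medians lay between 7.34 and 7.38, and arrays correlated at r = 0.9970 to 0.9983 within groups and at r = 0.9917 to 0.9942 between groups, across probe sets.

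GDC-0941 raised KLHL24 4.26-fold, CREBRF 4.02-fold, CCNG2 (cyclin G2, linked to cell cycle exit) 3.82-fold and IRS2 (an adaptor of the insulin and IGF receptors) 3.63-fold. YPEL2 rose 2.96-fold, SKAP2 2.86-fold, the antisense transcript SLC25A21-AS1 2.74-fold and CD55, which protects cells from complement, 2.73-fold. The largest falls were PHLDA2 (4.81-fold lower), PSAT1 (serine synthesis, 3.02-fold lower), HSPH1 (a heat shock protein, 2.87-fold lower) and CDC6 (loading of the replicative helicase, 2.73-fold lower). TNFRSF12A, the receptor of TWEAK, was 2.69-fold lower, MCM6 and MCM10 of the replication machinery 2.53-fold and 2.49-fold lower, and CTPS1, which makes CTP, 2.44-fold lower. KLHL24 had a level of 10.15 ± 0.09 under GDC-0941 and 8.06 ± 0.20 in controls (mean ± SD, n = 3 each), a log2 difference of 2.09 ± 0.09 (SE) with an adjusted p of 9.76e-08 in limma. PHLDA2 had 8.22 ± 0.03 against 10.49 ± 0.02 (mean ± SD, n = 3 each), a log2 difference of -2.27 ± 0.05 (SE) with an adjusted p of 1.04e-09. The adjusted p of these 16 genes was at most 4.86e-07 in limma. The fall of PHLDA2 rested on 1 of its 3 probe sets, as the others differed by 0.03 and -0.16 on the log2 scale without passing. Those others had mean levels of 6.585 and 4.064, below the median of 7.36 over all probe sets, against 9.353 for the one that fell. Whether they read the transcript is not known.

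**Figure D1:**
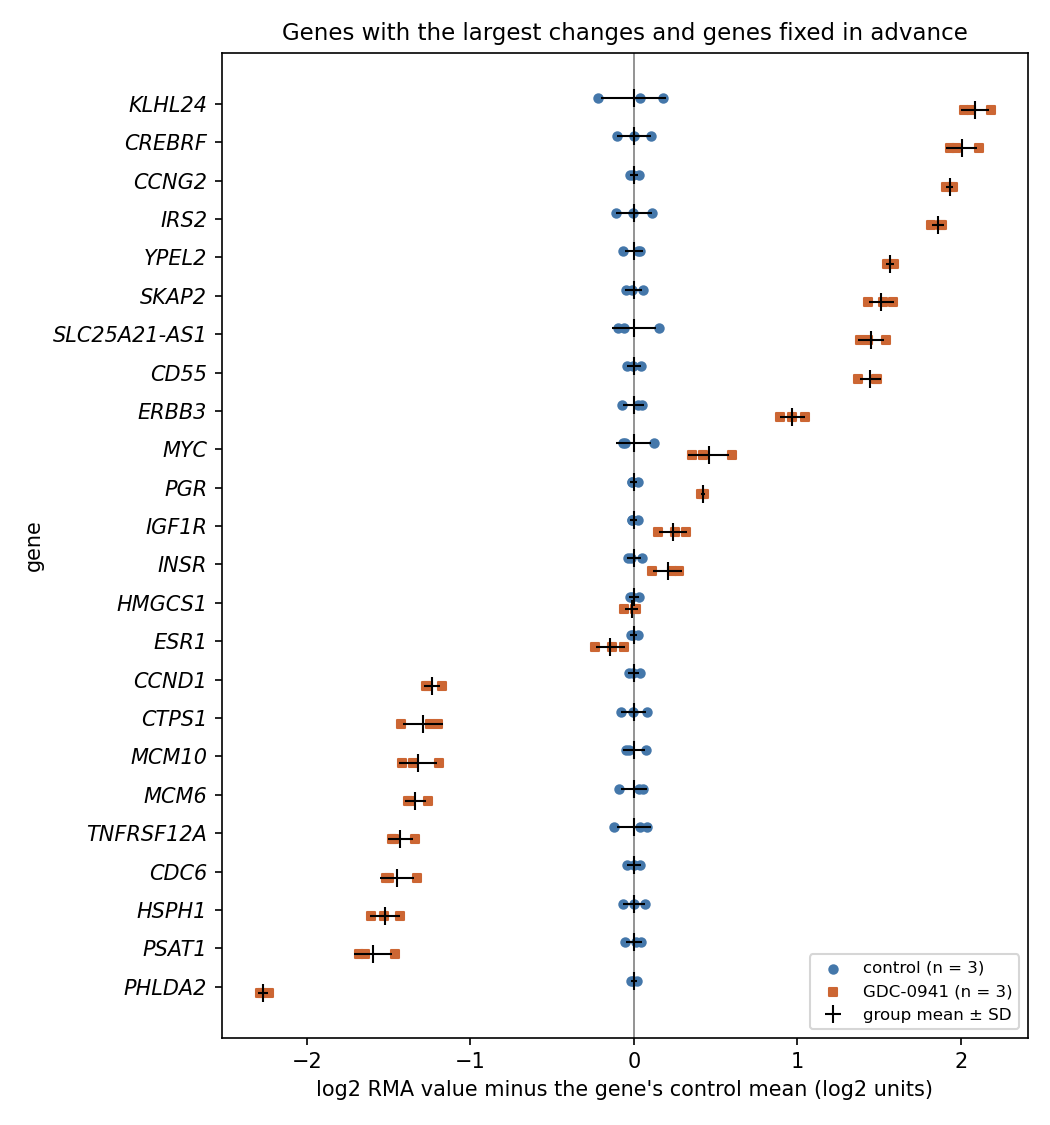
Log2 RMA value of each array minus the gene's control mean (x axis, log2 units) for the 16 genes with the largest changes and the fixed genes (y axis), with 3 control arrays as circles, 3 GDC-0941 arrays as squares, and group mean ± SD in black. The treated arrays of KLHL24, at a mean of 2.09, and of PHLDA2, at -2.27, lie far from the controls, while those of HMGCS1 and ESR1 lie near them.

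Over all 19775 genes, 5488 (27.8%) passed an adjusted p of 0.05 in limma, 2398 higher and 3090 lower after GDC-0941. Most changes were small: the median size was 0.31 on the log2 scale, and 73 genes passed with at least a 2-fold change, 39 higher and 34 lower. Of the 54613 probe sets, 10251 passed, 4851 higher and 5400 lower. In 41.5% of genes the 3 treated arrays all lay above or below the 3 controls, where chance gives 10%. The split of calls depends on the reference: 43.7% of the called genes were higher with the authors' normalization and 86.4% with each array centred on its hybridisation controls, which moved the median of all genes from -0.017 to 0.152. The directions below are relative to the other transcripts on the array. That centring ended the calls of KRT8, TPI1, CRELD2, ISG15, DUSP5, ACTA2, TNFAIP2, RPL22L1 and RPL26L1. The controls themselves did not shift evenly. Probe sets of cre, at 13.25 to 13.93 on the control arrays, differed by -0.029 to -0.084. Those of bioC, at 9.67 to 10.49, differed by -0.251 to -0.277. A single amount per array may thus be too large for bright genes such as KRT8 (13.72 in controls). Values with this centring are a check on the reference, not a better estimate. The calls of BOK, MRPL12, NDUFB7, SLC7A1, YARS1 and ZNF33B, like that of PHLDA2, were lost when probe sets that the manufacturer did not mark as matching several transcripts were taken first, and those of ACTA2, INSR, KLF4, TNFAIP2 and TNFAIP3 when all probe sets of a gene were averaged. Fold changes are those of the chosen probe set. Further genes had only 1 probe set called, among them DEPTOR and CCND3 (1 of 2) and GREB1 and TP53INP1 (1 of 3). None of their probe sets was called the opposite way.

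Targets of the FOXO factors, which AKT keeps out of the nucleus, formed the list with the largest rise. Of 23 measured targets, 20 rose and none fell, with a median log2 difference of 0.85 (21 higher and 1 lower adjusted over the list alone; 22 and 1 with the arrays centred on hybridisation controls, and 18 and 1 without treated replicate 1). KLHL24, CCNG2 and IRS2 led the list. The list passed camera (adjusted p = 8.52e-21) but not with an estimated correlation (adjusted p = 0.414 with an estimated correlation). None of the 37 sets passed that form of the test after adjustment, the smallest adjusted p being 0.414, and 3 had an unadjusted p under 0.05 in it. That form estimates the correlation from only 3 arrays per group, so it can miss real shifts. A failure in it, here or below, does not show that a set stayed unmoved. Of the 15 sets that passed camera, 14 also passed fry in the same direction. That adds little, as fry asks only whether a set moved by itself and 27.8% of all genes were called. Fry also passed 7 sets that camera did not. These were solute carriers (fry adjusted p = 0.000789), receptor tyrosine kinases and adaptors (0.00564), and the luminal, BCL2, interferon, xenobiotic and basal lists (0.0428 to 0.0429).

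Of 20 receptor tyrosine kinases and adaptors 9 rose and 4 fell (9 and 4 adjusted over the list alone; 10 and 1 with the arrays centred on hybridisation controls), and the list did not pass camera (adjusted p = 0.1). It passed with the arrays centred on hybridisation controls (camera adjusted p = 0.00306), with unmarked probe sets taken first (camera adjusted p = 0.00988) and by fry (adjusted p = 0.00564). The first of these does not show a larger shift relative to other genes, as that centring adds the same amount to every gene of an array. The list median went from 0.087 to 0.257 and that of all genes from -0.017 to 0.152. ERBB3 (HER3), a strong binder of PI3 kinase, rose 1.96-fold (log2 difference 0.97 ± 0.06 SE, adjusted p = 1.33e-06 in limma) from a control level of 11.85 ± 0.07 to 12.82 ± 0.08 (mean ± SD, n = 3 each). IGF1R rose 1.18-fold (adjusted p = 0.01) and INSR 1.15-fold (adjusted p = 0.0259). The INSR call was lost without treated replicate 1, treated replicate 3, control replicate 1 or control replicate 3 (adjusted p 0.0593 to 0.124). FGFR3 fell by 0.85 on the log2 scale. This list shares ERBB3, INSR and IRS2 with the FOXO list.

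Among 29 components of the PI3K-AKT-mTOR pathway, 10 rose and 3 fell (10 and 3 adjusted over the list alone; 15 and 2 with the arrays centred on hybridisation controls, where the median was 0.23). Of those that rose, PIK3IP1 and RICTOR are also members of the FOXO list. DEPTOR, an inhibitor bound to mTOR, rose 2.34-fold, FOXO3 1.90-fold and PIK3IP1, a negative regulator of PI3 kinase, 1.62-fold. The 3 that fell, given after their values were seen, were AKT1 (log2 difference -0.58), EIF4EBP1 (-0.43) and PHLPP2 (-0.335). The list passed camera (adjusted p = 0.0055) with a median of 0.06, but not with an estimated correlation (adjusted p = 0.809 with an estimated correlation). Without treated replicate 1 the median was 0.03 and the call was lost (adjusted p = 0.0613). The median was 0.035 without control replicate 1 and 0.13 without treated replicate 2, and the list passed camera in both (adjusted p = 0.0129 and 0.000676). With all arrays, the list median lay at percentile 98.47 of random lists matched on mean expression. It lay at percentile 93.33, inside their central range, with gene length matched as well.

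Genes of G1/S progression and DNA replication fell as a group: 25 of 28 were lower and none higher (26 and none adjusted over the list alone), with a median log2 difference of -0.61. CDC6, MCM6 and MCM10 fell most. The list passed camera (adjusted p = 4.27e-19), and not with an estimated correlation (adjusted p = 0.414 with an estimated correlation). Cyclin D1 (CCND1) was 2.35-fold lower, at 9.30 ± 0.05 against 10.54 ± 0.03 (mean ± SD, n = 3 each; adjusted p = 1.43e-07 in limma), and cyclin D3 (CCND3) 2.12-fold lower. The CDK inhibitor CDKN1B (p27) rose 1.85-fold. Among the 12 D-type cyclins and CDK inhibitors 4 rose and 3 fell (4 and 3 adjusted over the list alone), and the list did not pass camera (adjusted p = 0.789), with a median of 0.006 and a mean of -0.021. Opposite changes cancel in that test, so this does not show that the members stayed unchanged. Fry without regard to direction passed the list (adjusted p = 1.72e-05), but it passed 36 of the 37 sets. Of 24 genes of G2/M and mitosis 7 rose and 4 fell (8 and 4 adjusted over the list alone; 10 and 1 with the arrays centred on hybridisation controls). TOP2A rose 1.31-fold and HMMR 1.30-fold, CDC20 fell by 0.40 on the log2 scale, and the list did not pass camera (adjusted p = 0.274). Without treated replicate 2 it did (adjusted p = 0.0383).

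Genes that supply the cell with ribosomes and amino acids fell. In ribosome biogenesis 24 of 28 genes were lower and none higher (24 and none adjusted over the list alone; 14 lower and 1 higher with the arrays centred on hybridisation controls). NOP16 was 2.07-fold lower, LYAR 1.90-fold and RRS1 1.59-fold. The list passed camera (adjusted p = 9.63e-12; adjusted p = 0.509 with an estimated correlation). MYC, whose product drives many such genes, rose 1.37-fold (adjusted p = 8e-04). Of 24 genes of amino acid supply and ATF4 targets 19 fell and 3 rose (20 and 3 adjusted over the list alone). PSAT1 led the falls, followed by the amino acid transporters SLC7A1 (1.99-fold lower) and SLC1A5 (1.91-fold lower). The 3 that rose, given after their values were seen, were DDIT3 (log2 difference 0.73), NUPR1 (0.36) and MTHFD2 (0.34). The list passed camera (adjusted p = 3.96e-08; adjusted p = 0.548 with an estimated correlation). Of 17 cytosolic tRNA synthetases 14 were lower and none higher (16 and none adjusted over the list alone; 6 lower with the arrays centred on hybridisation controls), led by TARS1, YARS1 and GARS1 (1.70-fold, 1.60-fold and 1.56-fold lower). That list passed camera (adjusted p = 4.61e-08; adjusted p = 0.548 with an estimated correlation).

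Of 57 cytosolic ribosomal protein genes, none rose and 4 fell (none and 3 adjusted over the list alone; 6 rose and 1 fell with the arrays centred on hybridisation controls), with a median of 0.015 and a mean of -0.013, and the family did not pass camera (adjusted p = 0.789). RPL39L, RPL26L1 and RPL22L1, paralogs of the main ribosomal protein genes, had the largest falls, by 0.74, 0.33 and 0.24 on the log2 scale. Mitochondrial ribosomal protein genes fell in 56 of 72 cases and rose in 1 (60 and 1 adjusted over the list alone; 25 and 5 with the arrays centred on hybridisation controls), with MRPL12 1.90-fold, MRPL17 1.89-fold and MRPS12 1.76-fold lower. The 1 that rose, given after its value was seen, was MRPL10 (log2 difference 0.23). The family passed camera (adjusted p = 6.33e-17; adjusted p = 0.548 with an estimated correlation). Of 32 genes of respiratory complex I 23 fell and 1 rose (24 and 1 adjusted over the list alone; 6 and 3 with that centring; 14 and 1 without treated replicate 2 or without control replicate 3), with NDUFS6, NDUFB7 and NDUFV3 1.55-fold, 1.52-fold and 1.40-fold lower, and NDUFA5, chosen after its value was seen, higher by 0.305 on the log2 scale. This family passed camera (adjusted p = 1.23e-06; adjusted p = 0.548 with an estimated correlation).

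Proteasome genes fell in 31 of 42 cases and rose in none (32 and none adjusted over the list alone; 16 and 1 with the arrays centred on hybridisation controls). PSME3, PSMG3 and PSMB10 were 1.56-fold, 1.56-fold and 1.51-fold lower, and the family passed camera (adjusted p = 2.59e-12; adjusted p = 0.548 with an estimated correlation). Of 53 symbols of translation initiation factors 23 were lower and 7 higher (24 and 8 adjusted over the list alone), among them EIF5A2 and EIF2S2 (1.75-fold and 1.53-fold lower) and EIF3J-DT, a divergent transcript caught by the symbol rule (1.42-fold higher). The median was -0.129, and 0.040 with the arrays centred on hybridisation controls, where 15 were higher and 7 lower. Camera gave an adjusted p of 0.0323 (adjusted p = 0.921 with an estimated correlation), which was lost without treated replicate 2, treated replicate 3 or control replicate 3 (adjusted p 0.0623 to 0.130). Without treated replicate 1 the median was -0.20 and the list passed (adjusted p = 0.0024). The call was also lost with genes above the median level alone (adjusted p = 0.0565), with unmarked probe sets first (0.0588), with the array spread as a covariate (0.0885) and by fry (0.0712). Heat shock genes were lower in 9 of 10 cases and higher in none (9 and none adjusted over the list alone), led by HSPH1, DNAJA1 (2.20-fold lower) and HSPA4L (1.80-fold lower). They passed camera (adjusted p = 6.63e-08; adjusted p = 0.416 with an estimated correlation). In the unfolded protein response 5 of 16 genes rose and 5 fell (5 and 7 adjusted over the list alone; 6 and 2 with the arrays centred on hybridisation controls, and 3 and 4 without control replicate 2), with SDF2L1, MANF and CRELD2 lower by 1.03, 0.69 and 0.39 on the log2 scale, and the list did not pass camera (adjusted p = 0.789).

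Lysosome and autophagy genes, many of them targets of TFEB, rose in 20 of 27 cases and fell in 1 (22 and 1 adjusted over the list alone; 24 and none with the arrays centred on hybridisation controls), with a median log2 difference of 0.36. GPNMB rose 2.30-fold, FNIP1, a partner of folliculin, 2.13-fold and ATG14, needed to start autophagosomes, 1.70-fold. The 1 that fell, chosen after its value was seen, was GLA (-0.24). The list passed camera (adjusted p = 5.12e-13; adjusted p = 0.509 with an estimated correlation). Of 20 glycolysis genes 12 were lower and 2 higher (13 and 2 adjusted over the list alone), but 2 lower and 3 higher with the arrays centred on hybridisation controls. HK2 (hexokinase 2) was 2.06-fold, PFKP 1.71-fold and TPI1 1.29-fold lower, and the list passed camera (adjusted p = 0.00223; adjusted p = 0.548 with an estimated correlation).

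The lists of lipid synthesis genes did not pass camera. Of 19 genes of cholesterol synthesis and uptake 4 rose and 7 fell (4 and 9 adjusted over the list alone; 4 and 2 with the arrays centred on hybridisation controls, and 4 and 4 without treated replicate 2 or without control replicate 3), and camera gave an adjusted p of 0.483. INSIG1 rose 1.51-fold, ACAT2 and EBP were 1.42-fold and 1.37-fold lower, and HMGCS1, HMG-CoA synthase, differed by -0.01 ± 0.06 (SE, adjusted p = 0.906). Of 11 fatty acid synthesis genes LPIN1 rose and FASN fell (1 and 1 adjusted over the list alone; 4 and 1 with that centring), with log2 differences of 0.32 and -0.45 and a camera adjusted p of 0.890. The hypoxia list of 15 genes had 3 higher and 5 lower (4 and 6 adjusted over the list alone; 6 and 2 with that centring; 5 and 5 without treated replicate 2; camera adjusted p = 0.946), with VEGFA 1.68-fold and PDK1 1.59-fold lower and BHLHE40 1.58-fold higher. Among 342 solute carriers 26 rose and 67 fell (25 and 67 adjusted over the list alone; 72 and 23 with that centring; camera adjusted p = 0.187), and SLC52A2, SLC7A1 and SLC1A5 fell most (log2 differences -0.99, -0.99 and -0.94).

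Histone genes rose in 22 of 50 cases and fell in none (24 and none adjusted over the list alone). H2BC4 rose 2.41-fold, H2AC6 2.24-fold and H2BC21 2.10-fold, and the family passed camera (adjusted p = 1.32e-07; adjusted p = 0.414 with an estimated correlation). Histone genes are near-identical copies, and of their probe sets 11 of the 14 marked by the manufacturer as matching several transcripts were higher, against 10 of the 44 others. Of 466 C2H2 zinc finger genes 108 rose and 36 fell (113 and 38 adjusted over the list alone; 213 and 6 with the arrays centred on hybridisation controls), with ZNF750, ZNF33B and ZNF518A higher by 0.93, 0.91 and 0.90 on the log2 scale. This family passed camera (adjusted p = 7.41e-04; adjusted p = 0.548 with an estimated correlation), with a median of 0.05 (0.22 with that centring).

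**Figure D2:**
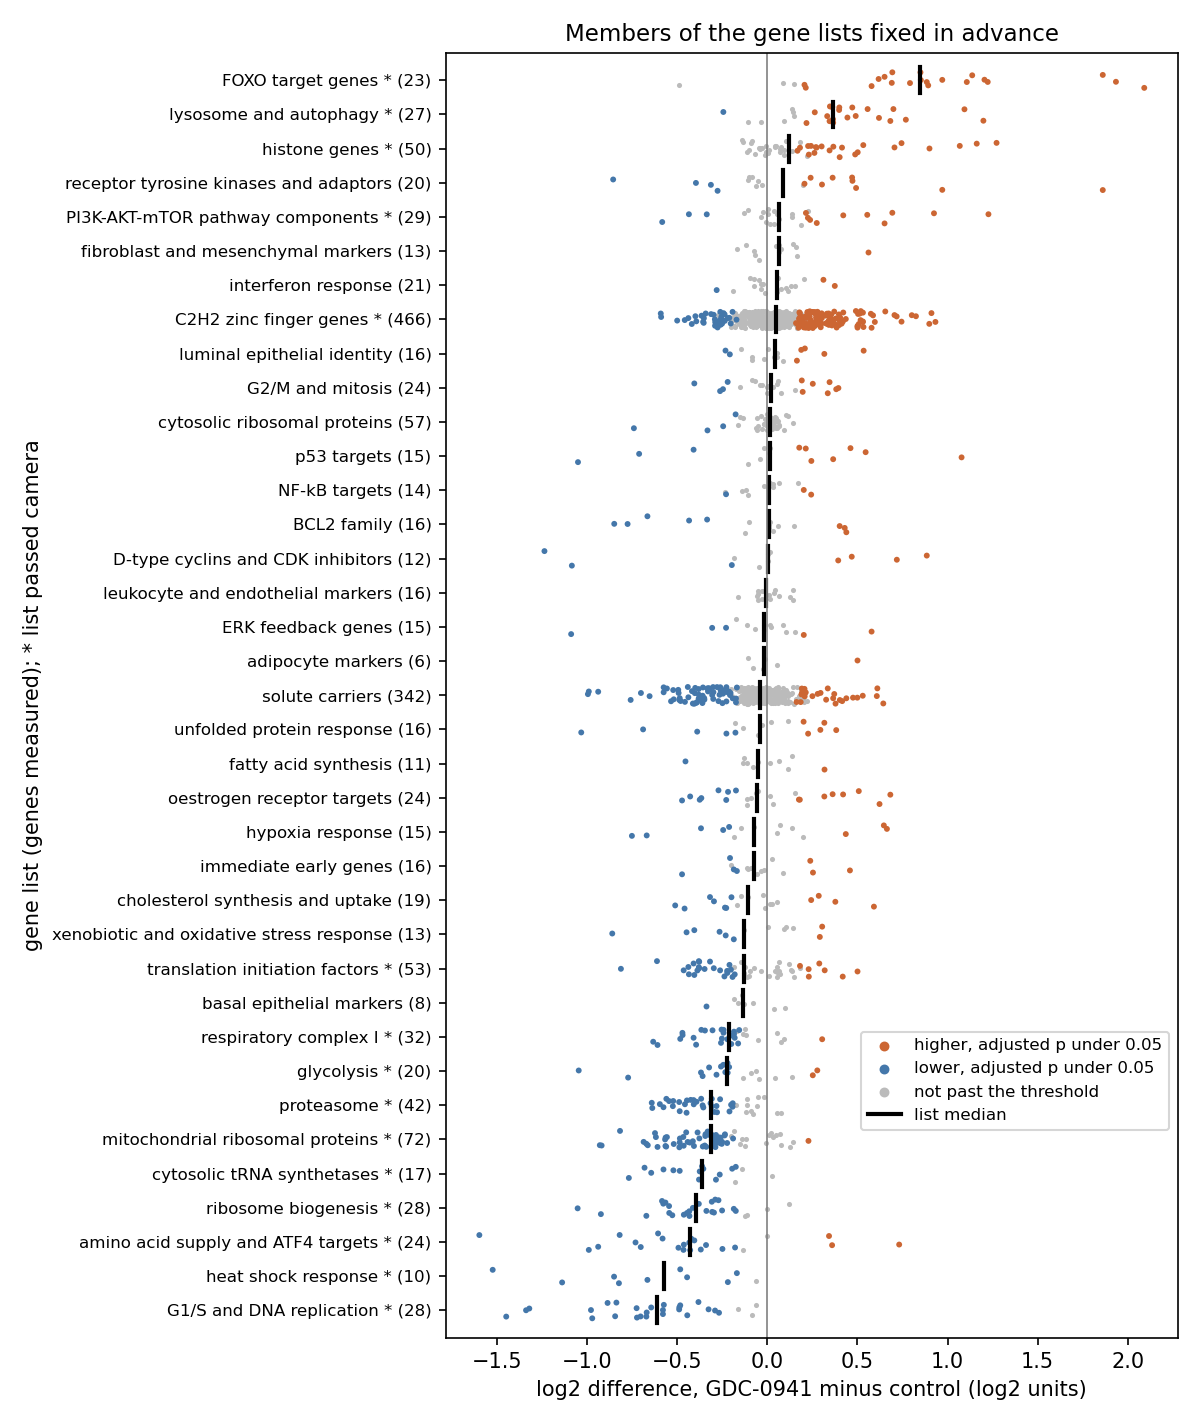
Log2 difference, GDC-0941 minus control (x axis, log2 units), of each measured member of the 37 gene lists and families (y axis, number of genes in brackets), orange or blue where the adjusted p was under 0.05, with the list median as a bar and an asterisk where the list passed camera. FOXO targets lie highest, with a median of 0.85, and G1/S genes lowest, with a median of -0.61; with the arrays centred on hybridisation controls the medians lie higher, and that of translation initiation factors is 0.040.

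Oestrogen receptor targets split evenly: of 24, 8 rose and 8 fell (9 and 8 adjusted over the list alone; 9 and 2 with the arrays centred on hybridisation controls), with a median of -0.057, a mean of 0.022 and a camera adjusted p of 0.789. GREB1 rose 1.61-fold, RERG 1.54-fold, NRIP1 1.42-fold and PGR, the progesterone receptor, 1.34-fold (adjusted p = 0.000117). ESR1, the oestrogen receptor itself, differed by -0.14 ± 0.06 (SE) on the log2 scale without passing (adjusted p = 0.109). It passed without treated replicate 1 (adjusted p = 0.0406), with a variance trend (0.0223), with array weights (0.0113) and with the array spread as a covariate (0.0456). Of 16 luminal identity genes 5 rose and 2 fell (5 and 2 adjusted over the list alone; 6 and none with that centring; camera adjusted p = 0.297), with FOXA1 1.45-fold and XBP1 1.25-fold higher and KRT8 lower by 0.23 on the log2 scale. Without treated replicate 3, 2 of them rose and 2 fell, and without any 1 control 3 rose and 2 fell.

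Feedback genes of the ERK pathway showed 2 rises and 3 falls among 15 (2 and 3 adjusted over the list alone; 5 and 1 with the arrays centred on hybridisation controls; 1 and 3 without treated replicate 1, 1 and 2 without treated replicate 2 or control replicate 1; camera adjusted p = 0.890), with log2 differences of -1.09 for SPRED1, -0.31 for DUSP5 and 0.58 for PHLDA1. Of 16 immediate early genes 3 rose and 4 fell (3 and 4 adjusted over the list alone; 4 and 1 with that centring; camera adjusted p = 0.789), among them MYC, EGR3 (log2 difference -0.47) and KLF4 (0.25). The KLF4 call was lost without control replicate 2 (adjusted p = 0.0625). That left 2 rises and 2 falls in the list, while leaving out treated replicate 2 or 3 left 3 and 2, and leaving out control replicate 1 left 3 and 1. Of 15 p53 targets 7 rose and 3 fell (7 and 3 adjusted over the list alone; 4 and 3 without control replicate 2; camera adjusted p = 0.205), with TP53INP1 2.11-fold higher and TIGAR and AEN 2.07-fold and 1.64-fold lower. In the BCL2 family 3 of 16 rose and 5 fell (4 and 5 adjusted over the list alone; camera adjusted p = 0.655), with the pro-apoptotic genes BID, PMAIP1 and BOK 1.80-fold, 1.71-fold and 1.58-fold lower. Its median was 0.011 and its mean -0.108, and opposite changes within it can cancel in camera.

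Among 21 interferon response genes 2 rose and 1 fell (2 and 1 adjusted over the list alone; 8 and none with the arrays centred on hybridisation controls; 2 and 2 without treated replicate 1; camera adjusted p = 0.367), namely IRF9 and HERC5 (0.38 and 0.31) and ISG15 (-0.28). Among 14 NF-kB targets 2 rose and 1 fell (2 and 1 adjusted over the list alone; 4 and none with that centring; none and 2 without treated replicate 2, 1 and 2 without control replicate 1, 1 and 1 without control replicate 2, none and 1 without control replicate 3; camera adjusted p = 0.882), namely TNFAIP3, ICAM1 and TNFAIP2 (0.24, 0.20 and -0.23). The calls of TNFAIP3 and ICAM1 were lost without treated replicate 2 (adjusted p = 0.0994 and 0.0624) and without control replicate 3 (0.0891 and 0.0507), that of TNFAIP3 also without control replicate 2 (0.106) and that of ICAM1 without control replicate 1 (0.0992). The median of the NF-kB list was 0.011 and its mean -0.005. Of 13 xenobiotic and oxidative stress genes 2 rose and 6 fell (2 and 6 adjusted over the list alone; 5 and 3 with the arrays centred on hybridisation controls; camera adjusted p = 0.393), with OSGIN1, SRXN1 and SLC7A11 lower by 0.86, 0.45 and 0.40 on the log2 scale.

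Among markers of other cell types, COL1A1 was the 1 gene called of 13 fibroblast and mesenchymal markers (1.48-fold higher; camera adjusted p = 0.393), and ACTA2 the 1 of 8 basal epithelial markers (1.26-fold lower; camera adjusted p = 0.318). ADIPOQ was the 1 of 6 adipocyte markers (1.41-fold higher, at 5.72 ± 0.09 against 5.22 ± 0.22, SD, n = 3 each; camera adjusted p = 0.816). None of 16 leukocyte and endothelial markers was called by limma and none had an unadjusted p under 0.05. HLA-DRA had the smallest (log2 difference 0.14, adjusted p = 0.146; called with the arrays centred on hybridisation controls, adjusted p = 0.00641, and with array weights, 0.0483), and camera gave an adjusted p of 0.789. These counts were the same adjusted over the list alone. With the arrays centred on hybridisation controls 7 fibroblast and mesenchymal, 4 leukocyte and endothelial, 1 basal and 1 adipocyte marker were called higher and none lower. Without treated replicate 1 or without treated replicate 2, 2 fibroblast and mesenchymal markers were higher, and without control replicate 3, 1 was higher and 1 lower. Without control replicate 1, 3 basal markers were lower, and without control replicate 2, 1 leukocyte and endothelial marker was lower. The median of the adipocyte list was -0.019 and its mean 0.054, and those of the leukocyte and endothelial list were -0.006 and 0.008.

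Array quality was compared through the manufacturer's controls. The difference between the 3' and 5' probe sets of ACTB, which grows as RNA is degraded, was 0.40 ± 0.01 on the GDC-0941 arrays and 0.27 ± 0.05 on the controls (SD, n = 3 each; exact permutation test, two-sided, p = 0.1, the smallest this design allows). That of GAPDH was -0.12 ± 0.01 and -0.14 ± 0.01 (exact permutation p = 0.2). The mean of the 18 hybridisation control probe sets was 10.74 ± 0.11 and 10.91 ± 0.02 (exact permutation p = 0.1), and all 18 were lower on the GDC-0941 arrays, by 0.03 to 0.28. They read few transcripts (bioB, bioC, bioD and cre), with several probe sets each, so they are not 18 independent measures. Treated replicates 1 and 2 had means of 10.72 and 10.647. Treated replicate 3, at 10.865, lay closer to the controls (10.898 to 10.941). The Benjamini-Hochberg adjusted values of these 3 tests, among 5 computed, were 0.25, 0.333 and 0.25. The ACTB values of the groups did not overlap, so an effect of RNA quality on any group difference above cannot be told apart from treatment.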

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

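Of the 11721 probe sets for which the platform annotation names no gene, 691 were higher and 407 lower after GDC-0941 at an adjusted p under 0.05 in limma. They were picked out because they lie outside the comparison of named genes, and 12 of them were higher and 1 lower by at least 2-fold. They were called less often than probe sets with 1 named gene, in 9.4% against 21.2% of cases. The share of higher among the called ones was 62.9%, against 45.6% among called probe sets with 1 named gene. They were not analysed by gene.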

How the results depend on the processing

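Centring on hybridisation controls and the array spread covariate were chosen after the data were examined; the other alternatives were planned. Called genes numbered 5488, and 4374 to 6749 under every alternative except array weights and an adjusted p under 0.01. Leaving out 1 array gave 4374 to 5321 called genes. With array weights, whose estimation stopped before it converged, 9411 genes (4235 higher, 5176 lower) and 16901 probe sets (7999 and 8902) passed. At an adjusted p under 0.01, 3701 genes and 6104 probe sets (2937 and 3167) passed, as a stricter limit must give fewer. Centring on hybridisation controls gave 5688 genes higher and 895 lower, 88 and 12 of them at least 2-fold, and 12875 and 1445 probe sets. That setting moved every gene by the same amount per array, so the order of genes within an array did not change. Of the 5488 called genes, 3292 passed under it, all in the same direction, and 46 changed sign without passing. With unmarked probe sets taken first 4647 of them passed, 4632 in the same direction, and 222 of the 5488 changed sign. With the mean of all probe sets of a gene, 44 genes passed at 2-fold, 21 of them higher, against 73 and 39, because probe sets of a gene that differ less were averaged in. Of the 37 gene sets 15 passed camera, 14 to 16 under the other fits, 0 (0 higher and 0 lower) with an estimated correlation, and 21 with fry, 8 higher. For the named genes 1745 of 1785 recomputed values kept their side of the threshold, and for the gene sets 633 of 666, including 6 and 26 that changed sign without passing either way. With probe sets not marked as shared taken first, the log2 differences of PHLDA2 and NDUFB7 were 0.026 and 0.065 without passing, since another probe set was read, and the calls of MRPL12, YARS1, BOK, SLC7A1 and ZNF33B were lost. The probe sets read then were dimmer. Those of PHLDA2, NDUFB7, BOK and ZNF33B had mean levels of 6.585, 5.778, 7.282 and 7.318, below the median of 7.36 over all probe sets. Those of MRPL12, YARS1 and SLC7A1 lay above it (7.593, 7.844 and 8.125). Of the 5 probe sets of SLC7A1, 3 were called lower. Centring on hybridisation controls ended 9 calls of named genes and started that of HLA-DRA, as it adds the same amount to every gene of an array. With the replicate block 4932 genes, 8514 probe sets and 15 gene sets passed, and INSR (adjusted p = 0.0568) and TNFAIP3 (0.051) lost their calls. Deviations of equally numbered arrays from their group means correlated at r = -0.34, 0.14 and -0.03 across probe sets. Those of differently numbered arrays of the 2 groups correlated at r = -0.363 to 0.354, and 1 of the 6 arrays correlated best with its own number. These values show no pairing by number. They cannot exclude one, as the arrays are few and deviations from a shared group mean depend on each other. With each array left out, the ACTB 3' minus 5' difference between the groups was 0.106 to 0.154 (0.137 with all arrays) and that of GAPDH 0.015 to 0.029 (0.022). RMA values carry no detection call, so the signal over background of single genes was not assessed.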

Other observations

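The gene groups of this part, their tests and the genes named here were chosen after the main results had been seen, although the members of the 4 lists were written before their own values were looked at. All 5 YPEL genes, a conserved family of small zinc-binding proteins, were higher: YPEL2 2.96-fold, YPEL3 2.33-fold, YPEL5 1.55-fold, YPEL1 1.31-fold and YPEL4 1.29-fold. YPEL3 is also a member of the FOXO list. Among the other genes that rose at least 2-fold were HBP1 (2.22-fold) and BTG1 (2.02-fold), both known to restrain proliferation, ARRDC3 (2.27-fold), an arrestin-domain protein, and CYBRD1 (2.26-fold), a ferric reductase. AMD1, an enzyme of polyamine synthesis, was 2.23-fold lower, LRP8, a lipoprotein receptor, 2.38-fold lower, and POLR3G, a subunit of RNA polymerase III, 2.04-fold lower.

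The fall of CTPS1 prompted a list of 18 other genes of nucleotide synthesis, of which 12 were lower and none higher, among them CAD (log2 difference -0.53), UMPS (-0.50), DHODH (-0.45) and PFAS (-0.42). Their median of -0.24 lay at percentile 0.04 of 10000 random lists matched on mean expression, which fits the hypothesis that the pathway fell as a class. Of 7 subunits of the cytosolic chaperonin 5 were lower and none higher, led by CCT6A (-0.59) and CCT5 (-0.49), with a median of -0.45 at percentile 0. A further list held 7 genes linked to polyamines other than AMD1, not all of them enzymes of polyamine synthesis. Of these 4 were lower, with SRM at -0.95, but the median of the 7, -0.19, lay at percentile 6.89, inside the range of random lists. For 18 splicing proteins 2 were higher and 3 lower, with a median at percentile 68.7. With camera the nucleotide, chaperonin and polyamine lists passed (adjusted p = 1.28e-05, 4.9e-05 and 0.0186 over the 4 lists), and all lost the call with an estimated correlation (adjusted p = 0.29 for each).

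Genes of the mitochondrial ribosome, respiratory complex I and the proteasome fell together, which could come from a trend of RMA values with expression level, since these genes are abundant, or from a bias with gene length, since many are short. Against the first, the highest of the 3 family medians lay at percentile 0.04 of random lists matched on mean expression. Against the second as the whole cause, it lay at percentile 0.23 when gene length was matched as well. A part from gene length stays open for mitochondrial ribosomal genes. The central range of their random lists matched on both lay wholly below zero change, from -0.146 to -0.003. Those of complex I (-0.16 to 0.035) and the proteasome (-0.126 to 0.035) spanned both signs. The values are relative to the other genes of an array, so they do not show whether the amounts per cell fell. The higher ACTB 3' minus 5' difference and a biological response to the inhibitor stay open, as neither was tested as the cause.

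The rise of histone genes could come from probe sets that match several histone transcripts, so that a few rising genes are counted many times. Of the 44 histone probe sets not marked in this way 22.7% were higher (exact 95% interval 11.5% to 37.8%, for counting error only), against 8.1% of all such probe sets, which argues against marked probe sets as the whole cause. Unmarked probe sets may still read several of these near-identical copies, so the comparison concerns the mark and cannot exclude shared signal. Among the 14 marked ones 78.6% were higher, so shared probes may still add to the count of 22 genes. A trend with expression level is argued against by the family's median, at percentile 100 of matched random lists. Whether polyadenylated histone transcripts increase in cells held before S phase was not tested.

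The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 5488 genes, 73 genes at 2-fold and 10251 probe sets, and in each case it was the 1 split with a count as large, the highest of the others being 0. These zeros carry little weight. Every other split mixes treated and control arrays, which puts any group difference into the spread within groups. For gene sets that passed camera 2 splits gave as many, as the real split gave 15 and the others 6 to 15. Every other split keeps part of the group difference, and camera's preset correlation lies below the correlation estimated here for all 15 passing sets. The median of a passing list was larger in the real split than in any other for 14 of the 15, the exception being the PI3K-AKT-mTOR components (0.06 against 0.10). This carries little weight, as these lists were picked because they passed in the real split, and every other split mixes the groups. Some lists that did not pass also had their largest median there, such as cholesterol synthesis and uptake (-0.106, against a size of at most 0.073 elsewhere). Others, such as G2/M and mitosis, did not (0.02 against 0.091).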
